A study of Mus musculus with 6 samples.

How the data were processed

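RNA-seq was done on 6 samples of RM-1 mouse prostate cancer cells, 3 carrying a Bhlhe22 lentivirus and 3 a blank vector lentivirus. The deposited table holds raw counts per gene, which the authors made with tools named in their processing notes as CASAVA 1.8, HISAT2 2.1.0, StringTie 1.3.4b and edgeR on the GRCm38 build, without saying which step used which. The table also holds FPKM values that the authors made from the same counts, per kilobase of 1 length per gene and scaled to the counts summed over the table. This was checked on the values: in 10435 of 10435 genes with at least 100 counts in every sample, count and FPKM gave the same length in all 6 samples within 0.001%. The table lists 55487 genes with Ensembl identifiers. The annotation release, filters and strandedness of counting are not given in the sources used here. Of these identifiers 55141 were also in GENCODE M21, 99.4% of them with the same coordinates and 96.7% with the same symbol. Strands, exon overlaps (bedtools 2.31.1) and the gene models of Bhlhe22 and Csf2 were taken from it. So were the length and GC content of each gene's longest transcript. Gene types and the positions of other genes came from the deposited table. Where a symbol belonged to more than 1 identifier (114 symbols), the one with the most counts was used.

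The comparison of Bhlhe22 with vector cells used edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr (minimum count 10, minimum total count 15), robust quasi-likelihood fits and Benjamini-Hochberg adjustment at 0.05. CPM values are on TMM-scaled library sizes. No covariate was used, since no label says that a replicate number marks a shared day or culture. The labels do not say whether the replicates were separate cultures, so the p-values rest on a spread between samples that may be technical. Where a group had 0 counts in every library, a fold was computed against 3 counts in each library, and this floor covers counting error only. At the depths sequenced the floor was 0.119 to 0.194 CPM per library. The fit was tested on simulated data with 3 samples per group. It recovered 22% of 100 genes changed 1.5-fold, 68% of 50 changed 2-fold and 98% of 50 changed 4-fold. In the single draw made 9.92% of its calls were false, which is above the threshold of 0.05. Only these genes and a further gene set were changed, far fewer than were called in the real data. Both groups were given the same spread for each gene, so these rates need not hold for the real fit.

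The comparison, the alternatives, the lists and the rule for named genes were set before the data were examined. The 34 gene lists came from textbook knowledge and cover myeloid factors, checkpoints, interferon, MHC class I, NF-kB, PRMT5 and related enzymes, basic helix-loop-helix factors, neuronal, epithelial and mesenchymal markers, matrix and its proteases, bone, prostate, cell cycle, p53, MYC, ERK, TGF-beta, WNT, NOTCH, hypoxia, cholesterol, oxidative phosphorylation, stress, heat shock, other cell types and controls. All 763 of their symbols were in the table. Counts given for a list refer to its members that passed the filter, and several lists lost many members to it. Those tested were 10 of 25 neuronal, 6 of 16 prostate basal, 10 of 21 androgen and luminal and 11 of 24 epithelial genes. They were also 12 of 23 osteoblast-like, 10 of 22 WNT and 13 of 25 basic helix-loop-helix genes. The 32 lists with at least 5 tested members were tested as sets with limma's camera (limma 3.58.1, preset correlation 0.01, two-sided, adjusted over the lists). Of the 7 lists past the threshold, 2 stayed past it with an estimated correlation. That setting raised the adjusted p even where the estimate was below the preset, as in the cell cycle list (0.0079). A call lost under it need not come from correlation between genes. The rule named Bhlhe22, Csf2 and Prmt5 in any case. It then took the 12 largest increases and 12 largest decreases among called protein-coding genes that were not predicted genes, had groups that did not overlap and reached a mean of 5 CPM in the higher group. From each list it took up to 4 called members with the smallest adjusted p.

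The alternatives were DESeq2 1.42.0, limma-voom, RLE, upper quartile and library size scaling, no filter, a filter of 1 CPM in 3 samples, fits without robust estimation, a replicate block, limma on log2 FPKM with a pseudocount of 1, glmTreat against a 1.2-fold change, protein-coding genes alone, leaving out each library, and for the lists an estimated correlation and fry. A correction for the trend of each library on GC content and gene length (splines with 5 degrees of freedom) and leaving out genes that share exons were added after seeing the data. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. All 6 samples and all count columns were used.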

Results

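RNA was sequenced from RM-1 cells, a mouse prostate cancer cell line, carrying a lentivirus for Bhlhe22 (called Bhlhe22 cells) or a blank lentiviral vector (vector cells), with 3 libraries per group. Bhlhe22 is a basic helix-loop-helix transcription factor known from neuronal development. The counts summed to 17950347, 20446128 and 21223227 in vector replicates 1, 2 and 3 and to 15464709, 19548474 and 25129552 in Bhlhe22 replicates 1, 2 and 3. Between 20047 and 21913 genes had at least 1 count in a library. The title of the series ties Bhlhe22 to the infiltration of bone metastases by myeloid-derived suppressor cells, and the comparison asks which genes differ between the 2 kinds of cancer cell in culture.

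Bhlhe22 itself was the first check of the labels. It had 0 counts in all 3 vector libraries and 8706, 14785 and 17995 counts in Bhlhe22 replicates 1, 2 and 3, or 684 ± 99.9 CPM (counts scaled to library size; SD, n = 3) and 203 ± 30.5 FPKM. Against a floor of 3 counts in each vector library, Bhlhe22 was at least 4538-fold higher (edgeR adjusted p = 4.7e-05), and it ranked 144 among all genes in these cells. The gene (ENSMUSG00000025128) lies on the plus strand of chromosome 3 from 18054174 to 18057517 in GRCm38 and has 1 exon, whose coding part runs from 18054788 to 18055852 between a 5′ and a 3′ UTR. Gene counts cannot separate transcripts of the lentivirus from those of the chromosomal gene.

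Counting Bhlhe22 itself, 1520 genes were higher and 1361 lower in Bhlhe22 cells among 14663 tested (edgeR quasi-likelihood test, Benjamini-Hochberg threshold 0.05), which was 19.6% of them. The change was at least 2-fold in 315 of the higher and 211 of the lower genes. In 2880 of the 2881 called genes the 3 values of one group lay outside the range of the other. The same held for 40.8% of all tested genes, where chance gives 10%. After Bhlhe22, the largest increases by the rule used were in genes with little expression in vector cells. Car6, a secreted carbonic anhydrase, went from 0.346 ± 0.229 to 31.3 ± 12.1 CPM (log2 fold change 6.52, SE 0.47, edgeR adjusted p = 2.8e-04), and without vector replicate 1 its log2 fold change was 7.15. Mamdc2 went from 0.129 ± 0.0674 CPM, on counts of 1, 3 and 4, to 10.2 ± 1.03 CPM. Saa3, an acute-phase serum amyloid, rose 16.2-fold to 8.30 ± 2.67 CPM, Avil, which encodes the actin-binding protein advillin, 15.6-fold to 21.9 ± 2.04 CPM, and Angptl6, a secreted angiopoietin-like factor, 17.6-fold to 32.8 ± 7.71 CPM. P2rx3, an ATP-gated channel of sensory neurons, had a log2 fold change of 3.46 and Extl1, a glycosyltransferase of heparan sulfate synthesis, of 3.08. Sh2d6, Cox6a2, Akr1b7 and Pla2g2e rose by 9.49-fold to 20.9-fold, of which Akr1b7 shares 27.2% of its exon length with a gene on the other strand, as Angptl6 does for 16.8%. Whether reads were counted by strand is not given in the sources used here, so the values of genes with such overlaps are less certain.

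Among called genes with a mean of at least 5 CPM in the higher group, the largest decreases by the same rule were smaller in size. Apln, the gene of the peptide hormone apelin, fell from 10.5 ± 1.51 to 2.66 ± 0.116 CPM (log2 fold change -1.98, SE 0.15, edgeR adjusted p = 3.3e-04), and Syt13, a synaptotagmin, had a log2 fold change of -1.97. Pclaf, a PCNA-binding factor of DNA replication, fell from 203 ± 4.02 to 55.1 ± 3.66 CPM (log2 fold change -1.88, SE 0.08). The replication licensing factor Cdc6 (-1.68), the cohesion factor Dscc1 (-1.56), the uracil-DNA glycosylase Ung (-1.66), the histone gene H2bc21 (-1.71), the imprinted gene Peg3 (-1.71), the splicing regulator Mbnl3 (-1.94) and the small heat shock gene Hspb1 (-1.79) also fell, all values being log2 fold changes. Idi1, an enzyme of isoprenoid synthesis, had a log2 fold change of -1.68 but lost its call without Bhlhe22 replicate 1 (-1.80, edgeR adjusted p = 0.094) and with no filter (0.075), and the 3 Bhlhe22 libraries spread from 30.8 to 82.9 CPM. Pcdhgc5 (-1.96) is uncertain, since 39.6% of its exon length is shared with genes on the same strand and its vector values ran from 16.4 to 67.9 CPM. Of the 6 fits that left out 1 library, it kept its call in the one without vector replicate 1 (-2.33), while its log2 fold change ranged from -2.04 to -1.38 and its edgeR adjusted p from 0.069 to 0.181 without vector replicate 2 or 3 or any 1 of the Bhlhe22 replicates. It was also not called by limma-voom (adjusted p = 0.061), by edgeR with no filter (0.145) or by limma on FPKM (0.069).

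**Figure D1:**
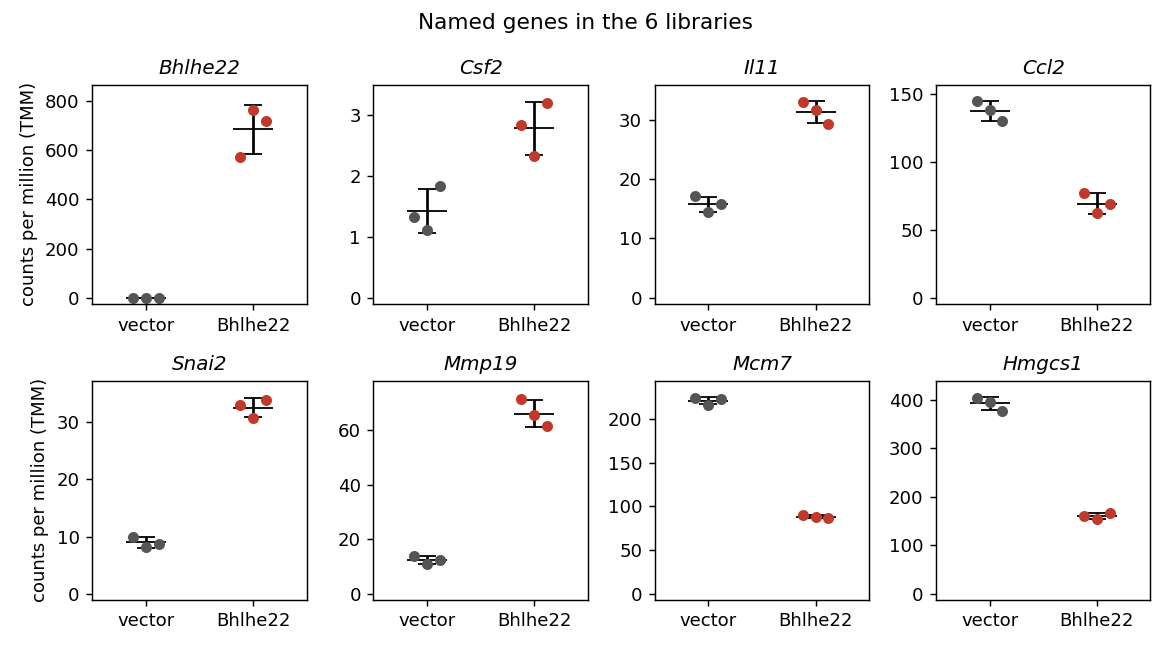
Values of 8 named genes in each library, in CPM on TMM-scaled library sizes, in vector cells (grey points) and Bhlhe22 cells (red points), with the mean and SD of each group of 3 as black bars. Bhlhe22 had 0 counts in the vector libraries, and in each of the 8 genes the points of the groups do not overlap.

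Cell cycle genes fell together. Of the 34 genes fixed for this list, 33 fell, 0 rose and 1 did not pass the test, with a median log2 fold change of -0.77 (camera adjusted p = 4.6e-37, and adjusted p = 0.005 with an estimated correlation), and 34 fell when adjusted over the list alone. The list holds genes of the replication helicase, of nucleotide supply and of mitosis. The helicase gene Mcm7 fell from 221 ± 4.20 to 88.2 ± 1.68 CPM (log2 fold change -1.33, SE 0.06, edgeR adjusted p = 6.0e-05). Mcm4 (-1.15), Mcm5 (-1.11), the ribonucleotide reductase subunit Rrm2 (-1.07) and the cyclin Ccne1 (-1.27) also fell, as did the mitotic genes Bub1b (-0.57), Plk1 (-0.51) and Ccnb1 (-0.43), all in log2 fold change. Ccne1 and these mitotic genes were chosen after their values were seen. The proliferation marker Mki67, chosen in the same way, went from 461 ± 15.9 to 240 ± 43.7 CPM. Ccnd1, the cyclin D1 gene of the WNT list, fell from 310 to 202 CPM (log2 fold change -0.62), with 23.4% of its exon length shared with a gene on the other strand. Leaving out each library in turn left between 28 and 34 genes of the list called, all lower.

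Genes of cholesterol synthesis and uptake fell by a similar amount. Of 25 genes, 19 fell, 0 rose and 6 did not pass the test, with a median log2 fold change of -0.77 (camera adjusted p = 1.6e-25, and adjusted p = 0.005 with an estimated correlation), and 21 fell when adjusted over the list alone. Hmgcs1, which makes the precursor of mevalonate, fell from 393 ± 13.5 to 161 ± 6.50 CPM (log2 fold change -1.29, SE 0.07, edgeR adjusted p = 8.4e-05). The feedback regulator Insig1 (-1.17) and Acat2 (-1.51, chosen after its value was seen) had the same direction. Between 16 and 22 members were called without each library in turn.

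Genes of the unfolded protein and integrated stress response were higher. Of 30 genes, 16 rose, 1 fell (Sdf2l1, chosen after its value was seen) and 13 did not pass the test, with a median log2 fold change of 0.43 (camera adjusted p = 1.1e-08). The list's call was lost with an estimated correlation (camera adjusted p = 0.131), and 17 rose and 1 fell when adjusted over the list alone. The stress transcription factor gene Atf3 rose from 28.1 ± 3.65 to 90.8 ± 2.82 CPM (log2 fold change 1.69, SE 0.11, edgeR adjusted p = 1.7e-04), Ddit3, which encodes CHOP, had a log2 fold change of 1.29, Dnajb9 of 1.15, and the amino acid transporter subunit Slc3a2 of 0.72. Without Bhlhe22 replicate 1 the list had 19 higher and 3 lower genes, and without any other library 11 to 15 higher and 0 lower, where Sdf2l1 had an edgeR adjusted p of 0.079 to 0.112.

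Heat shock genes, counted apart from that list, were lower in 6 of 16 cases and higher in 0 (7 and 0 when adjusted over the list alone), with a median log2 fold change of -0.30 (camera adjusted p = 0.0013, and adjusted p = 0.404 with an estimated correlation). The chaperone Hspa8 fell from 808 ± 6.50 to 418 ± 49.1 CPM (log2 fold change -0.95, SE 0.09, edgeR adjusted p = 8.9e-04) and its co-chaperone Hsph1 by 0.65 on the log2 scale. The count was 3 without any 1 vector replicate, 4 without Bhlhe22 replicate 2, 6 without Bhlhe22 replicate 3 and 10, with 1 gene higher, without Bhlhe22 replicate 1, out of 17 tested genes without vector replicate 2 or any 1 Bhlhe22 replicate. In the hypoxia and glycolysis list 10 of 30 genes rose and 1 fell, with the same counts when adjusted over the list alone and a median log2 fold change of 0.073 (camera adjusted p = 0.027, and adjusted p = 0.468 with an estimated correlation). The list's camera adjusted p was 0.071 without vector replicate 2 and 0.070 without Bhlhe22 replicate 1, and its median was 0.11 without vector replicate 3 and 0.12 without Bhlhe22 replicate 2. Among its higher genes were Ero1l, an oxidase of the endoplasmic reticulum (log2 fold change 1.47), Ndrg1, from 238 ± 10.4 to 546 ± 12.2 CPM, and the angiogenic factor gene Vegfa, from 207 ± 5.08 to 315 ± 21.4 CPM (0.61), while the gene that fell was the glycolytic Pgam1 (-0.32), chosen after its value was seen. Its number of higher genes was 6 without any library but Bhlhe22 replicate 1, and 12 without that one, where 5 were lower. Of these 6 fits, Pgam1 was called in the one without that library, with an edgeR adjusted p of 0.063 to 0.130 in the other 5.

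The androgen receptor and prostate luminal list had 3 genes higher and 1 lower of 10 (4 and 1 when adjusted over the list alone), with a median log2 fold change of 0.29 (camera adjusted p = 0.0032, and adjusted p = 0.321 with an estimated correlation). That median was 0.11 over the 10 genes tested without Bhlhe22 replicate 2. It was 0.64 without vector replicate 3 and 0.50 without Bhlhe22 replicate 1, where 11 genes passed the filter, so these are not medians of the same 10 genes. The higher genes were Ndrg1, which is also in the hypoxia list, the membrane protein gene Steap1 (from 34.7 ± 1.74 to 109 ± 14.5 CPM, log2 fold change 1.65) and the exporter Abcc4 (0.84). The androgen-responsive Fkbp5 fell by 0.25 on the log2 scale. Of the 6 fits that left out 1 library, Fkbp5 was called in the one without Bhlhe22 replicate 1, with edgeR adjusted p from 0.089 to 0.136 in the other 5. It was also not called with no filter (0.080) or with the replicate block (0.102). Of 6 prostate basal genes 2 rose and 0 fell (2 and 0 when adjusted over the list alone), with a camera adjusted p of 0.414. Lamb3 (log2 fold change 0.51), a subunit gene of a basement membrane laminin, was called with all 6 libraries but not without any 1 of them, with edgeR adjusted p from 0.056 to 0.151. With all 6 libraries it was also not called by DESeq2 (adjusted p = 0.112), nor by edgeR with upper quartile scaling (0.052), library size alone (0.053), no filter (0.086) or the replicate block (0.118). The list's count was 0 without any 1 vector replicate or Bhlhe22 replicate 2 and 1 without Bhlhe22 replicate 3. Without Bhlhe22 replicate 1 the count was 3 and the list was called (median log2 fold change 0.49, camera adjusted p = 0.028).

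**Figure D2:**
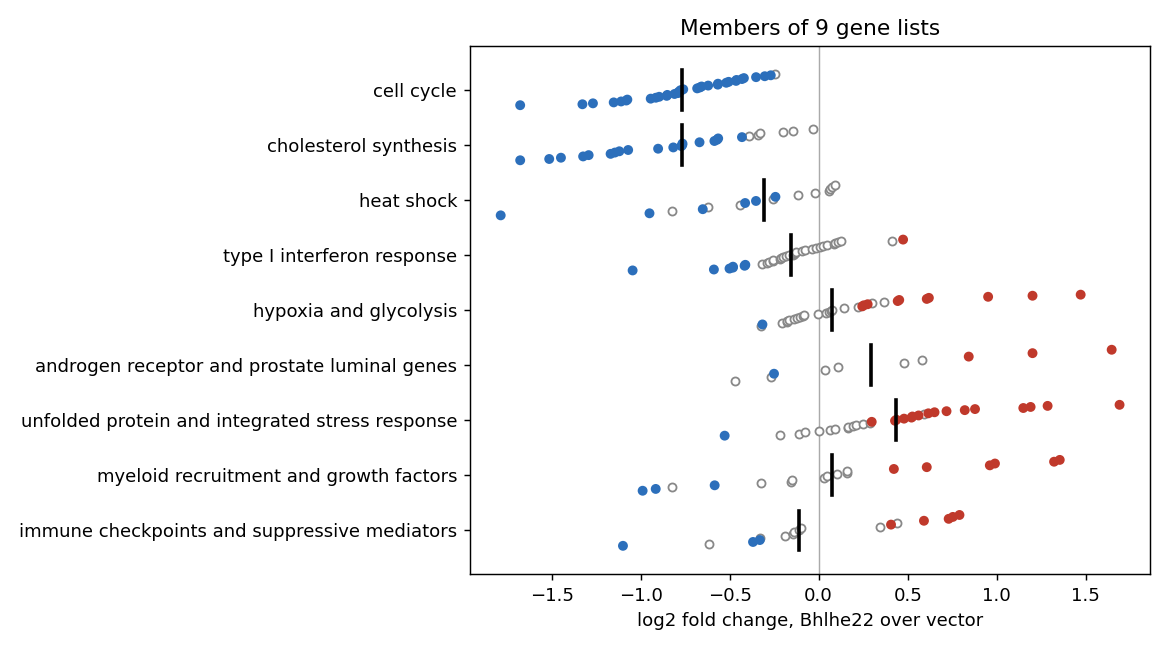
Log2 fold changes of Bhlhe22 over vector cells for the tested members of 9 gene lists, 1 point per gene, red where the gene rose, blue where it fell and open where it did not pass the edgeR test. The black bar is the list's median, at -0.77 for the cell cycle and cholesterol synthesis lists and at 0.43 for the stress response list.

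Factors that recruit or expand myeloid cells moved in both directions. Of 18 tested, 6 rose, 3 fell and 9 did not pass the test, the counts being the same when adjusted over the list alone, and the list as a whole was not called (median log2 fold change 0.07, camera adjusted p = 0.754). Csf2, which encodes the cytokine GM-CSF, is on the minus strand of chromosome 11 from 54247271 to 54249667 and has 4 exons. It had 24, 23 and 39 counts in the vector libraries and 43, 45 and 80 in the Bhlhe22 libraries, or 1.42 ± 0.363 and 2.78 ± 0.433 CPM (log2 fold change 0.96, SE 0.24, edgeR adjusted p = 0.033). The call rests on few counts. It was lost without vector replicate 1 (adjusted p = 0.118), vector replicate 2 (0.114), Bhlhe22 replicate 2 (0.053) or Bhlhe22 replicate 3 (0.097), with log2 fold changes from 0.81 to 1.19 over the 6 edgeR fits that each left out 1 library. Il11, a cytokine of the IL-6 family, rose from 15.7 ± 1.32 to 31.3 ± 1.92 CPM (log2 fold change 0.99, SE 0.10, edgeR adjusted p = 9.6e-04). The monocyte chemoattractant Ccl2 fell from 137 ± 7.35 to 69.3 ± 7.41 CPM (log2 fold change -0.99, SE 0.10, edgeR adjusted p = 8.1e-04), and the neutrophil chemoattractant Cxcl1 fell from 40.4 ± 1.58 to 26.9 ± 0.661 CPM (-0.58). Ccl7, chosen after its value was seen, had a log2 fold change of -0.92. The other higher genes were Il34 (0.42), Il6 (1.32) and Cxcl2 (1.35), all chosen after their values were seen and each called in 3 of those 6 fits. Il11, Vegfa, Ccl2, Cxcl1 and Ccl7 kept their calls without each library in turn, and the number of higher genes was 3 without vector replicate 1 or 2 or Bhlhe22 replicate 2, and 4 without vector replicate 3 or Bhlhe22 replicate 3.

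Immune checkpoint and suppressive genes were likewise split, with 5 higher and 3 lower of 17 (6 and 4 when adjusted over the list alone, camera adjusted p = 0.664). The list's median log2 fold change was -0.11 while its mean was 0.04 and its test pointed up. Ptgs2, the inducible prostaglandin synthase COX-2, rose from 419 ± 21.5 to 725 ± 69.3 CPM (log2 fold change 0.79, SE 0.09, edgeR adjusted p = 0.0015). Nectin2, a ligand of lymphocyte receptors, had a log2 fold change of 0.73 and Gdf15, a stress-induced cytokine, of 0.59. The increases in Cd274, which encodes PD-L1 (0.75, edgeR adjusted p = 0.010), and in Pvr (0.41) complete the count, and both genes were chosen after their values were seen. Cd24a fell from 11.1 ± 0.553 to 5.19 ± 0.333 CPM (-1.10). Lgals9 (-0.33) and Tgfb3 (-0.37), chosen in the same way, complete the lower genes, each called in 2 of the 6 fits that left out 1 library. Without Bhlhe22 replicate 1 the list had 4 lower genes, without vector replicate 1 or Bhlhe22 replicate 3 it had 2, and without vector replicate 2 or 3 or Bhlhe22 replicate 2 it had 1.

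Of 34 genes of the type I interferon response, 1 was higher and 7 were lower (1 and 7 when adjusted over the list alone), with a median log2 fold change of -0.15 (camera adjusted p = 0.038, and adjusted p = 0.567 with an estimated correlation). Cxcl10, a T cell chemoattractant, fell from 28.9 ± 0.513 to 14.0 ± 1.28 CPM (log2 fold change -1.04, SE 0.10, edgeR adjusted p = 6.8e-04), and the interferon-induced genes Dhx58 (-0.42) and Gbp3 (-0.48) fell less. The list's camera adjusted p was 0.130 without vector replicate 2 and 0.071 without Bhlhe22 replicate 2. The number of lower genes was 13 without Bhlhe22 replicate 1 and 3, 4, 5, 4 and 7 without vector replicates 1, 2 and 3 and Bhlhe22 replicates 2 and 3. The higher gene, Ifi44 (0.47, chosen after its value was seen), was not called without vector replicate 1 or 3 or Bhlhe22 replicate 2, with edgeR adjusted p from 0.067 to 0.089. In the MHC class I list 2 of 19 genes were higher and 3 lower (2 and 3 when adjusted over the list alone, camera adjusted p = 0.673), of which the non-classical class I gene H2-M3 (0.75) held without each library in turn. That list had 3 higher and 9 lower genes without Bhlhe22 replicate 1, 2 and 2 without Bhlhe22 replicate 3, and 1 and 1 without any other library. In the NF-kB target list 2 of 19 were higher and 3 lower (4 and 4 when adjusted over the list alone, camera adjusted p = 0.664), of which Plau (-0.71), the urokinase gene, Nfkbia (-0.42) and Cd40 (0.89) held without each library in turn. Its higher count was 1 without vector replicate 3 or Bhlhe22 replicate 2, and its lower count was 2 without vector replicate 1 or 2 and 5 without Bhlhe22 replicate 1.

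Genes of epithelial and mesenchymal identity changed singly. Snai2, a transcription factor of epithelial-mesenchymal transition, rose from 8.96 ± 0.926 to 32.6 ± 1.62 CPM (log2 fold change 1.86, SE 0.11, edgeR adjusted p = 1.3e-04) in a list with 3 of 22 genes higher and 4 lower (3 and 5 when adjusted over the list alone, camera adjusted p = 0.832). The matrix protein gene Thbs1 of the same list fell (-0.76). Without any 1 vector replicate the list had 2 higher and 1 lower genes, without Bhlhe22 replicate 2 it had 2 and 3, and without Bhlhe22 replicate 3 it had 3 and 2. Among 11 epithelial genes 1 was higher and 4 lower (2 and 4 when adjusted over the list alone, camera adjusted p = 0.255). Among the lower genes were the junction gene Ocln (-1.18), the keratin gene Krt8 (-0.47) and the transcription factor Grhl2 (-0.66), all 3 called without each library in turn. The higher one, Krt19 (0.40, chosen after its value was seen), was not called without any 1 vector replicate, with edgeR adjusted p from 0.063 to 0.074. Of 19 matrix proteases and inhibitors 4 were higher and 4 lower (6 and 5 when adjusted over the list alone, camera adjusted p = 0.595). Mmp19 rose from 12.3 ± 1.43 to 66.1 ± 5.01 CPM (log2 fold change 2.42, SE 0.12, edgeR adjusted p = 6.1e-05), with 28.3% of its exon length shared with a gene on the other strand, and the collagenase Mmp13 rose from 9.92 ± 1.03 to 22.6 ± 1.52 CPM (1.18). Without any 1 vector replicate or Bhlhe22 replicate 2 that list had 2 higher genes, with 1 lower in the vector cases and 2 in the other. The 21 collagen and matrix genes had 4 higher and 2 lower (4 and 5 when adjusted over the list alone, camera adjusted p = 0.999), with a median log2 fold change of 0.04 and a mean of -0.07, where the test pointed up. Their higher count was 0 without vector replicate 2, 1 without vector replicate 1 or 3 or Bhlhe22 replicate 2, 2 without Bhlhe22 replicate 3 and 9 without Bhlhe22 replicate 1. Their lower count was 1, 0, 0, 4, 1 and 4 without vector replicates 1, 2 and 3 and Bhlhe22 replicates 1, 2 and 3.

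Lists related to bone, the site named in the series title, gave mixed counts. Of 12 osteoblast-like genes 4 were higher and 1 lower (5 and 2 when adjusted over the list alone, camera adjusted p = 0.266). Spp1, which encodes osteopontin, rose from 846 ± 43.6 to 1227 ± 85.1 CPM (log2 fold change 0.54), Bmp6 by a log2 fold change of 0.54, and the alkaline phosphatase gene Alpl from 0.388 ± 0.135 to 2.96 ± 0.185 CPM. Of the sequence that Spp1's exons cover, 18.8% is shared with a gene on the same strand. Among 10 osteoclast-activating and bone metastasis factors 4 were higher and 3 lower (4 and 3 when adjusted over the list alone, camera adjusted p = 0.923). Their median log2 fold change was 0.13 and their mean 0.05, while the test pointed down. The matricellular genes Ccn2 (-1.16, from 90.4 ± 1.63 to 40.5 ± 2.13 CPM, with 23.2% of its exon length shared with a gene on the other strand) and Ccn1 (-0.69) fell, while Il11 and Gdf15 rose, and all 4 kept their calls without each library in turn. The osteoblast-like list had 0 lower genes without vector replicate 2 or 3 and 3 without Bhlhe22 replicate 1. The other list had 2 higher genes without vector replicate 1 or 2 or Bhlhe22 replicate 2, and 2 lower without vector replicate 1 or 2.

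Of 13 basic helix-loop-helix factors and partners, Bhlhe22 rose and 3 genes fell (2 and 5 when adjusted over the list alone, camera adjusted p = 0.127). The set test includes Bhlhe22 itself and pointed up, so neither that value nor the camera adjusted p of 0.0187 with the replicate block describes the other members. The lower genes were Id2 (-0.51), Id4 (-2.03) and Bhlhe40 (-0.49), of which Id2 and Id4 encode inhibitors of such factors. The list's median log2 fold change was -0.03, and its mean was 0.72 with Bhlhe22 at its bound and -0.23 without Bhlhe22. Without vector replicate 1 none of these 3 was called, with edgeR adjusted p from 0.0516 to 0.0895. One of the 3 was called without vector replicate 2 or 3 or Bhlhe22 replicate 2, and 5 genes of the list were lower without Bhlhe22 replicate 1. Of 25 neuronal and neuroendocrine markers 10 passed the filter. Of those tested, 2 rose, Eno2 (0.93) and Insm1 (1.36), and 0 fell (2 and 0 when adjusted over the list alone, camera adjusted p = 0.569). Prmt5, an arginine methyltransferase, had 166 ± 0.567 CPM in vector and 154 ± 4.17 CPM in Bhlhe22 cells (log2 fold change -0.10, SE 0.06), which did not pass the test (edgeR adjusted p = 0.287). In the list of its complex and related enzymes 4 of 12 genes were higher and 0 lower (4 and 0 when adjusted over the list alone, camera adjusted p = 0.399). These were Prmt2 (0.47), Prmt3 (0.39), Prmt7 (0.38) and Riok1 (0.35). None of the 4 was called without vector replicate 1 or 2, with edgeR adjusted p from 0.0522 to 0.0938, and 2 were called without vector replicate 3. Riok1 was also not called without Bhlhe22 replicate 3 (edgeR adjusted p = 0.0524) or with the replicate block (0.0621).

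In the remaining signalling lists no set was called. The p53 targets had 4 genes higher and 4 lower of 23 (7 and 6 when adjusted over the list alone, camera adjusted p = 0.375), with Gadd45a, a growth arrest gene, rising from 57.9 ± 3.42 to 178 ± 24.2 CPM (log2 fold change 1.62, with 19.1% of its exon length shared with a gene on the other strand), Plk2 (0.60) and Rrm2b (0.81) higher and Ckap2 (-0.57) lower. MYC targets had 3 higher and 1 lower of 25 (2 and 1 when adjusted over the list alone, camera adjusted p = 0.664). ERK pathway output had 4 higher and 2 lower of 22 (5 and 2 when adjusted over the list alone, camera adjusted p = 0.625), with the growth factor gene Areg (0.64) and Spry4 (0.66) higher. The TGF-beta and BMP response had 2 higher and 5 lower of 21 (2 and 5 when adjusted over the list alone, camera adjusted p = 0.138), with Smad6 at -0.76. WNT response had 0 higher and 2 lower of 10 (1 and 2 when adjusted over the list alone, camera adjusted p = 0.399), the lower ones being Ccnd1 and the receptor gene Fzd2 (-0.91). NOTCH response had 2 higher and 3 lower of 11 (2 and 3 when adjusted over the list alone, camera adjusted p = 0.595), with Nrarp at -0.69 and 79.4% of its exon length shared with a gene on the other strand. In the TGF-beta and BMP list and in the NOTCH list the higher count was 0 without any library but Bhlhe22 replicate 1, and 4 and 3 without that one. In the MYC list it was 0 without vector replicate 1, 1 without vector replicate 2 or 3 or Bhlhe22 replicate 2, and 6 without Bhlhe22 replicate 1. In the p53 list it was 7 without Bhlhe22 replicate 1, and the lower count was 2 without any 1 vector replicate. In the ERK list the higher count was 2 without vector replicate 1, and the lower count was 0 in that case and 1 without vector replicate 2 or 3 or Bhlhe22 replicate 2. The lower counts of the MYC, TGF-beta and BMP, and NOTCH lists were 0, 2 and 1 without vector replicate 1, 0, 2 and 2 without vector replicate 2, 0, 3 and 2 without vector replicate 3, 4, 6 and 4 without Bhlhe22 replicate 1, and 1, 3 and 2 without Bhlhe22 replicate 2.

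Neither the lists meant as controls nor the oxidative phosphorylation list was called as a set. The median log2 fold changes were 0.07 for mitochondrially encoded, 0.15 for cytosolic ribosomal protein, 0.02 for oxidative phosphorylation and -0.14 for housekeeping genes. Of 15 mitochondrially encoded genes 0 were called in either direction by edgeR (0 and 0 when adjusted over the list alone, 2 at an unadjusted p under 0.05, 0 by DESeq2, limma-voom and limma on FPKM; camera adjusted p = 0.925). Of 40 cytosolic ribosomal protein genes 0 were higher and 1 lower (0 and 0 when adjusted over the list alone, camera adjusted p = 0.364), the lower one being Rpl27 (-0.41). Of 31 oxidative phosphorylation genes 2 were higher and 1 lower (0 and 0 when adjusted over the list alone, camera adjusted p = 0.999), namely Uqcrq (0.68), Ndufa2 (0.49) and Sdhd (-0.36). The numbers of lower genes in these 3 lists were 2, 4 and 10 without Bhlhe22 replicate 1 and 0 without any other library. The higher count of the oxidative phosphorylation list was 0 without vector replicate 2 or 3, where Uqcrq had edgeR adjusted p of 0.073 and 0.071, and 1 without vector replicate 1 or Bhlhe22 replicate 2. Ndufa2 was not called in any of these 4 fits (edgeR adjusted p from 0.098 to 0.151), nor with all 6 libraries by limma-voom (0.053), by edgeR with upper quartile scaling (0.052) or by limma on FPKM (0.057). With the replicate block Rpl27 was not called (edgeR adjusted p = 0.067). Among 15 housekeeping genes 1 was higher and 4 lower (1 and 4 when adjusted over the list alone, camera adjusted p = 0.163). The share called was above the 19.6% of all tested genes. The transferrin receptor gene Tfrc went from 96.1 ± 2.22 to 41.1 ± 3.91 CPM (log2 fold change -1.23) and Gusb had a log2 fold change of -0.69. Ppia (-0.38) and Pgk1 (0.25, chosen after its value was seen) were called in all 6 libraries together but, with 1 left out, only without Bhlhe22 replicate 1. Actb was at -0.61, and was not called without any 1 of the 6 libraries (edgeR adjusted p from 0.057 to 0.092). With the replicate block neither Ppia (edgeR adjusted p = 0.072) nor Actb (0.075) was called. Markers of other cell types were mostly too low to test, as 5 of 18 macrophage and myeloid, 1 of 16 lymphocyte and 3 of 15 endothelial and erythroid markers passed the filter. The 3 endothelial and erythroid markers had 0 calls by edgeR (0 when adjusted over the list alone, 0 at an unadjusted p under 0.05, 0 by DESeq2 and by limma-voom). Cd74 rose from 3.46 ± 0.140 to 11.8 ± 0.520 CPM and Lck from 6.34 ± 0.719 to 11.9 ± 1.03 CPM, while Ly6g fell from 18.2 ± 1.86 to 7.36 ± 0.610 CPM. The 5 macrophage and myeloid markers as a set had a camera adjusted p of 0.832, a median log2 fold change of -0.14 and a mean of 0.03 with the test pointing up, and their counts, like those of the lymphocyte markers, were the same when adjusted over the list alone.

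Bhlhe22 replicate 1 stood apart within its group. Between library pairs, the chi-square per degree of freedom was 10.8 to 11.7 within the vector group and 13.6 between Bhlhe22 replicates 2 and 3, but 35.7 and 47.3 between Bhlhe22 replicate 1 and the other 2. Over 10358 genes with a mean of at least 8 CPM, the median SD of log2 CPM was 0.075 in vector and 0.151 in Bhlhe22 cells. Without Bhlhe22 replicate 1, 2345 genes were higher and 2337 lower. Leaving out vector replicates 1, 2 and 3 gave 715, 781 and 794 higher and 633, 677 and 686 lower genes, and leaving out Bhlhe22 replicate 2 gave 908 higher and 803 lower. Without each library in turn, the cell cycle list median stayed between -0.77 and -0.72.

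**Figure D3:**
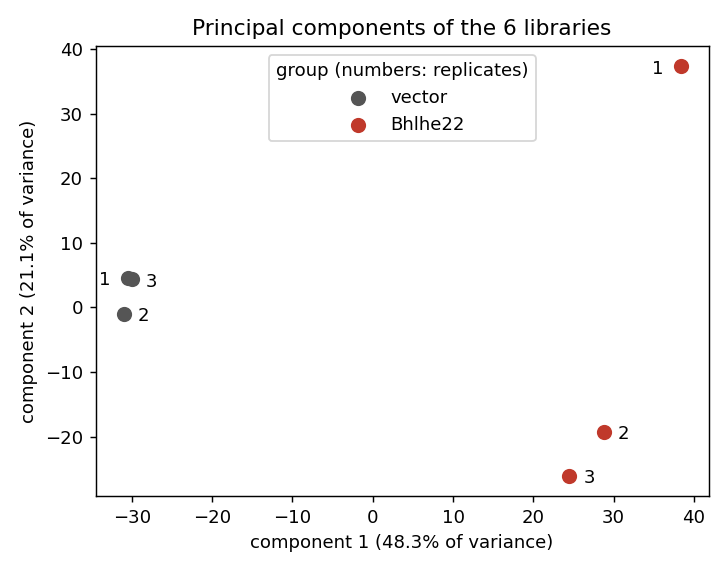
Principal components of the log2 CPM of the 6 libraries, with component 1 (48.3% of the variance) on the horizontal and component 2 (21.1%) on the vertical axis, vector libraries in grey, Bhlhe22 libraries in red, and the replicate number beside each point. Component 1 separates the groups, at -31.0 to -30.0 for vector and 24.5 to 38.3 for Bhlhe22 cells, and component 2 separates Bhlhe22 replicate 1 (37.3) from replicates 2 (-19.2) and 3 (-26.1).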

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

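The alternatives for GC content and length and for genes that share exons were chosen after seeing the data, the others were not. No gene called in the comparison was called in the opposite direction under any alternative. Of the 128 named genes called, 125 stayed called with DESeq2, 126 with limma-voom, 121 with limma on FPKM, 123 with no filter, 116 with the replicate block, 127 with GC and length trends removed and 89 with glmTreat. Testing against a 1.2-fold change (glmTreat) left 685 genes higher and 579 lower, since that test asks for more than a difference from 0. With limma on log2 FPKM, 103 genes were at least 2-fold higher and 58 at least 2-fold lower, where the pseudocount of 1 shrinks folds of weak genes. Without each library in turn, the number of higher genes ranged from 715 (without vector replicate 1) to 2345 (without Bhlhe22 replicate 1) and that of lower genes from 633 to 2337 in the same fits. The Csf2 log2 fold change ranged from 0.81 to 1.19 in those 6 fits, 4 of which lost its call, and the edgeR, DESeq2 and limma adjusted p ranged from 0.0233 to 0.118 over its 17 alternatives. With an estimated correlation, camera lost the calls of the lists for interferon (median -0.15, adjusted p = 0.567), androgen and luminal genes (0.29, 0.321), hypoxia (0.073, 0.468), stress response (0.43, 0.131) and heat shock (-0.30, 0.404), whose medians do not depend on that choice. In the cell cycle list the estimated correlation (0.0079) was below the preset 0.01, yet the camera adjusted p rose from 4.6e-37 to 0.005. These losses therefore cannot be put down to correlation between genes alone. Without each library in turn, the interferon median ranged from -0.20 to -0.14 and the hypoxia median from 0.061 to 0.12, with some calls lost in both. The cause was not tested. With the GC and length trends removed 2223 genes were higher and 1925 lower, and with the replicate block 1086 were higher and 993 lower. The correlations within replicate numbers were 0.029, 0.021 and 0.016, so no effect shared by samples of 1 number was visible. They cannot show whether the samples were paired by day or culture, which the labels leave open. fry, which does not compare a list with other genes, passed the threshold for 9 lists that camera did not call, among them the basic helix-loop-helix list, which includes Bhlhe22 itself. Genes such as Csf2, with 23 to 80 counts per library, may be limited by depth, which was not tested.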

Other observations

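The tests on genes whose counts jumped between libraries were chosen only after the result was seen. The tests on the other lists were written before their values were seen, though after the first fit of the same libraries. They are therefore not an independent check. Their genes lie outside the fixed lists, except the chaperones Calr and Pdia3, which are in the MHC class I list. DNA replication genes outside the cell cycle list fell in 27 of 30 cases (median log2 fold change -0.83), with Chaf1b, a histone chaperone subunit, at -1.54 and the checkpoint mediator Clspn at -1.43. Mitotic genes outside it fell in 21 of 28 cases (median -0.53). The medians differed by -0.30 (permutation p = 7.9e-04, two-sided, genes not being independent), the replication genes falling more. A change that weighs more on S phase than on mitosis is a candidate explanation. Cell cycle phase was not measured, so RNA counts alone cannot test it. Leaving out each library in turn left 22 to 28 and 19 to 25 of these genes called.

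Of 17 fatty acid synthesis genes 10 fell (median log2 fold change -0.44), among them Fasn (-1.47), Acaca (-0.82) and Elovl6 (-1.02), so sterol and fatty acid synthesis may have fallen together. That count was 6 without any 1 vector replicate and 13 without Bhlhe22 replicate 1. In a list mainly of genes for amino acid synthesis, transport and tRNA charging, 18 of 23 rose (median 0.60). Among them were Cth at 2.03, Wars at 1.29 and Pycr1 at 1.13. In a list of endoplasmic reticulum chaperones and related genes of that compartment, called the chaperone list, 4 of 16 rose (median 0.14). The medians differed by 0.46 (permutation p = 7.6e-04, genes not being independent). The 4 higher genes of the chaperone list, not all of them chaperones, were Selenos (0.81), Sil1 (0.64), Hyou1 (0.38) and Erp44 (0.28). The chaperone list leaves out genes held in the fixed stress list, such as Hspa5 and Dnajb9, of which Dnajb9 rose. The difference therefore cannot tell an amino acid response from an unfolded protein response. The chaperone count was 9 without Bhlhe22 replicate 1, 2 without vector replicate 3 and 1 without vector replicate 1 or 2 or Bhlhe22 replicate 2.

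The joint fall of cell cycle and cholesterol genes was weighed against technical explanations. With each library's trend on GC content and gene length removed, the list medians were -0.74 for the cell cycle and -0.75 for cholesterol synthesis, which argues against such a trend as their whole cause. Across 10349 genes, the Spearman correlation of gene length with a library's deviation from its group mean was -0.65, 0.47 and 0.59 in Bhlhe22 replicates 1, 2 and 3 and -0.15, 0.21 and -0.077 in vector replicates 1, 2 and 3. Deviations within a group cancel for each gene, so a trend in 1 library brings opposite trends in the others. The values of Bhlhe22 replicates 2 and 3 need not be trends of their own. Without Bhlhe22 replicate 1 the medians were -0.74 and -0.75, which argues against that library alone. An effect of Bhlhe22, of growth state at harvest or of the viral infections stays open, since each group holds 1 kind of virus. Among the 10 splits of the 6 libraries into 3 and 3, 1 gave as many called genes as the real one, itself (2881, the highest other 3), and 10 splits are too few for a share under 0.05. Every other split mixed the groups, so the group difference itself widened the spread and kept calls low. The other splits therefore cannot show how many calls arise without a group difference.

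Some genes jumped between near 0 and full counts in single libraries. Gm50241 had 2542, 2994 and 61 counts in Bhlhe22 replicates 1, 2 and 3 and 48 to 78 in vector libraries, and was called (log2 fold change 5.12, edgeR adjusted p = 0.0398). The overlapping gene Chtf8 had 219, 298 and 3765 in the same Bhlhe22 replicates and 2657 to 3453 in vector libraries. Their sum differed by a log2 ratio of 0.14 between groups, so reads may have moved between the gene models in the counting. Among genes with a mean of at least 8 CPM, a 4-fold range within a group occurred in 14 of 106 genes that share 50% or more of their exons and in 50 of 10252 others (odds ratio 31.0, Fisher's exact p = 1.8e-15, two-sided, genes not being independent). Genes that share exons can exchange reads and so jump together, and the pair that prompted the test was not left out. Tlr4 (69 counts in Bhlhe22 replicate 1, 1004 to 1514 elsewhere) and Eif3j2 (0 in Bhlhe22 replicates 2 and 3, 1057 to 1345 elsewhere) jumped without such an overlap, chosen after their values were seen, and 2 called genes had such a range.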
